A study of Salmonella enterica subsp. enterica serovar Cerro with 4 samples.

How the data were processed

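Genomic DNA of Salmonella enterica serovar Cerro strain 87, a strain that carries phosphorothioate bonds in its DNA backbone, was mapped with Nick-seq, which turns a modification into a strand nick and reads the nick's position by sequencing. Per the labels' protocols, the DNA was cut with restriction enzymes, existing breaks were blocked with chain-terminating nucleotides, and iodine then cleaved the phosphorothioate bonds. The nicks were read in 2 ways. In the nick translation (NT) preparation, DNA polymerase I extended from the nick with nuclease-resistant thio-nucleotides and exonucleases removed the template. The other library type depended on terminal transferase (TdT), an enzyme that adds nucleotides to free 3′ ends. Each preparation had 1 library labelled iodine and 1 labelled negative control, 4 libraries in all. The labels give the controls no treatment, while the protocol describes an NT control taken after nick conversion and given water in place of the polymerase, so whether the NT control met iodine is not settled by the sources used here.

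The deposited 5′ coverage tables hold, for each strand and each of 4602439 positions of 1 chromosome sequence, the whole-number count of reads whose 5′ end lies there. The deposited full coverage tables, used here for the 2 controls, hold the read depth signal per position and strand. No normalization is recorded for either. The submitters' processing notes name Trim Galore, Bowtie2 and bedtools; their versions and settings, including the treatment of duplicate and multiply mapping reads, are not given in the sources used here. Rises in the deposited forward depth and falls in the reverse depth followed the 5′ counts across positions (Pearson's r between 0.989 and 1.00), so a reverse-strand read starts at its highest coordinate. All coordinates below count from 1 on the sequence the files use.

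The calling rule was fixed before the data were examined. A strand position was called where the iodine count was at least 10 and at least 5 times the library's mean per strand position, where the iodine count plus 1 over the library total was at least 2 times that of the control, and where the count was the highest within 2 positions on the same strand. The same rule was run with iodine and control exchanged, which counts calls in the opposite direction; it is no null where the control itself carries ends at the sites. NT and TdT calls were joined at the strand relation and offset, within 20 positions, that held the most coincident calls, and the overlap of independent lists was set beside it. The sites named are the 10 shared sites with the highest lower value of the 2 iodine rates, in counts scaled to the library total (CPM); the rule also asked for the sequence motif, which was not applied. Each group had 1 library, so no test across samples and no p-value was possible. Shares have Wilson 95% intervals and site averages have 95% intervals from 1000 resamplings of sites. Both cover counting error or spread over sites within these libraries, not differences between cultures, and reads without molecular identifiers are not independent molecules.

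Several measures were chosen after the calls had been seen. TdT calls on opposite strands with the reverse end 3 positions below the forward end were joined as strand pairs, and a pair's level was the geometric mean of its 2 iodine counts. Pairs with a level of at least 128 counts, 13.4 CPM, were called high-level and the others low-level. This border was chosen because the distribution of levels had the lowest point between its 2 peaks next to that value. Read ends of all libraries were averaged around the pairs with both strands turned to the read direction. Position 0 is the pair's end on the opposite strand, and the position after it, 1, is called the nick position. Averages over wider windows set counts above 1000 at a position to 1000. Spacing was set against 1000 random placements and against 1000 random draws of as many pairs from all pairs.

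The calling rule was tested on simulated data drawn from the pooled rates of each preparation at the real depths. Planted pairs were added to the iodine library alone, at random positions and with the TdT pair distance of 3 in both preparations. Recovery where the control carries many ends of its own was therefore not simulated. Of 50 planted pairs with 20 added ends per strand, 46 were recovered in the NT simulation and 48 in the TdT simulation, and all 50 with 50 or more added ends. With no difference simulated, the rule still made 10053 NT calls and 3635 TdT calls over 9204878 strand positions, but 5 NT and 12 TdT strand pairs. Alternatives covered the minimum count, the ratio, the control filter, the local maximum rule, scaling, pseudocount, the offset tolerance and the number of bins. Results that need the genome sequence or its annotation (the motif, restriction sites, genes, gene lists and repeats) were planned and are not analysed here, because no sequence of this build was used. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.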

Results

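The series mapped phosphorothioate bonds, in which sulfur replaces a non-bridging oxygen of the DNA backbone, at single positions in Salmonella enterica serovar Cerro 87. The NT control held 8476936 mapped 5′ ends and the NT iodine library 9667810, which is 0.921 and 1.05 ends per strand position. The TdT control held 4075700 ends and the TdT iodine library 9566066. Median read depth over both strands was 40 in the NT control and 8 in the TdT control. Ends were far more concentrated in the TdT libraries: the 1000 fullest strand positions held 53.6% of the TdT control's ends and 24.5% of the TdT iodine library's, against 4.65% and 1.85% in the NT control and NT iodine libraries. There was 1 library per group, so every difference below compares libraries and has no replicate check.

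The first comparison asked where iodine created read ends in the TdT preparation. Iodine gave 24377 TdT sites, 12271 on the forward and 12106 on the reverse strand, and the exchanged comparison gave 14352. The sites were organised by strand. A reverse-strand site lay exactly 3 positions below a forward-strand site in 9304 cases, where independent lists would give 32.3 and where the fullest other offset within 20 positions held 141. These pairs took up 76.3% of the TdT sites (Wilson 95% interval 75.8 to 76.9). The exchanged comparison gave 28 such pairs. In this strain phosphorothioate bonds are known to follow the G of GAAC on one strand and of its complement GTTC on the other; the sequence at the pairs was not analysed here.

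Most ends of the TdT iodine library lay at these pairs. The paired strand positions make up 0.202% of all strand positions. They held 61.8% of the TdT iodine library's ends (61.7 to 61.8) but 0.399% of the control's (0.393 to 0.405). After scaling this is a ratio of 155 (148.6 to 161.6 over resampled pairs). The TdT control was not empty there. At high-level pairs it had 0.386 CPM at the paired ends (0.367 to 0.406), against 0.0674 CPM 10 to 60 positions upstream. At low-level pairs the values were 0.0948 and 0.0601. No control end on either strand was found at 16.3% of high-level pairs. The remaining 5769 TdT sites had no called partner, but 87.7% of them (86.8 to 88.5) had at least 1 end 3 positions away on the other strand, with a median of 5.

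The strand pairs fell into 2 levels. The number of pairs per log2 step of 0.5 peaked at 1260 between 4 and 4.5, dropped to 220 between 7 and 7.5 and peaked again at 857 between 9 and 9.5. There were 3820 high-level pairs, 41.1% of all pairs (40.1 to 42.1), with a median level of 558 counts, and 5484 low-level pairs with a median of 27.0. The calling minimum of 10 counts per strand cuts off the lower end of these levels. The number and median of low-level pairs and the 41.1% share therefore depend on it. With a minimum of 5 there were 11606 pairs, 3820 of them high-level, and with 20 there were 6475, with 3819 high-level. High-level pairs alone held 57.2% of all TdT iodine ends. Iodine raised the rate at the paired ends 194-fold at high-level pairs (184.3 to 203.4) and 44.0-fold at low-level pairs (41.4 to 46.6); the calls required iodine above control and the levels were set by the iodine count, so a larger fold at high-level pairs follows from the definition. Forward and reverse counts of a pair differed by a median log2 ratio of 0.06 at high-level pairs with an SD over sites of 1.54, and by 0.00 with an SD of 1.23 at low-level pairs.

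**Figure D1:**
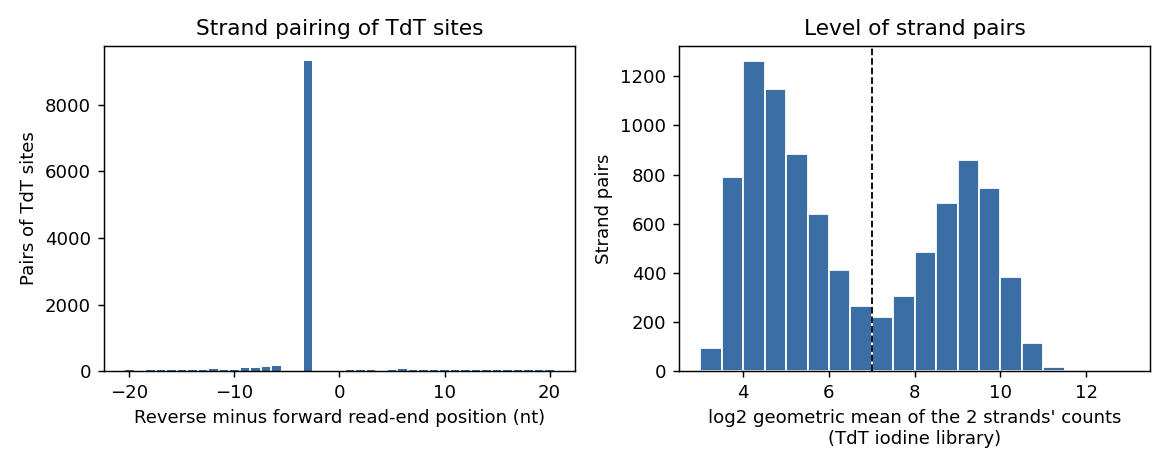
Left, number of forward and reverse TdT sites at each offset of the reverse from the forward read end in nucleotides; the bar at -3 holds 9304 pairs. Right, strand pairs by log2 geometric mean of the 2 strands' counts in the TdT iodine library; the dashed line marks 7, the border between 5484 low-level and 3820 high-level pairs.

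The second comparison asked the same of the NT preparation. Iodine gave 19258 NT sites, 9744 on the forward and 9514 on the reverse strand, with a median count of 12. The exchanged comparison gave 37733 sites, more than the iodine comparison itself. Simulated libraries with no difference gave 10053 NT calls. NT sites held 3.35% of the NT iodine library's ends.

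The overlap of the preparations asked whether both place nicks at the same bases. The most coincident calls lay on the same strand, with the TdT end 2 positions downstream of the NT end. There were 343 such shared sites, 6.73 times the 51.0 of independent lists, and offsets 10 to 20 positions away held 26 to 83. Nearer offsets formed a second group. On the same strand, TdT ends 3, 2 and 4 positions upstream of the NT end held 244, 186 and 148 coincident calls. Where the TdT end is in a strand pair, these NT ends fall within the window 5 to 10 positions downstream of the site. In that window the NT iodine library was the higher one on average, as given below. The cause of this group was not tested. The 343 shared sites made up 1.78% of NT sites and 1.41% of TdT sites. Of the 343 shared sites, 307 had their TdT end in a strand pair and 248 in a high-level pair. The opposite strand with the TdT end 1 position upstream held 325. A strand pair's other end lies 3 positions back, so this is largely the same relation seen through the pair. NT positions called in the exchanged comparison, with more ends in the control, lay at the shared relation 1319 times, 13.2 times the 99.9 of independent lists.

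All 10 named shared sites were in high-level strand pairs, and the NT rate was the lower one at each. The first was on the forward strand, with the NT end at 4159731 and the TdT end at 4159733. It had 125 NT iodine ends against 29 in the control, or 12.9 against 3.42 CPM (counts scaled to the library total), and 1559 TdT iodine ends against 6, or 163 against 1.47 CPM. The second was on the reverse strand, with the NT end at 1802911 (124 ends against 12) and the TdT end at 1802909 (1239 against 5). The reverse-strand site with its TdT end at 3641869 and the forward-strand site with its TdT end at 4305729 each had 99 NT iodine ends against 12, and the latter had 448 TdT iodine ends against none in the control. Forward-strand TdT ends at 2237764 had the highest TdT count of the 10, 3489 against 4, with 76 NT iodine ends against 1. The other 5 had TdT ends at 89258 on the reverse strand and at 1422500, 2064468, 1279189 and 2559938 on the forward strand, with 75 to 93 NT iodine ends and 357 to 2017 TdT iodine ends. What genes lie at these positions was not analysed here.

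Averaged over strand pairs instead of called one by one, both NT libraries carried a signal at the TdT-defined sites. At high-level pairs the NT control had a mean of 1.39 CPM at the nick position (1.21 to 1.62) and the NT iodine library 0.484 CPM (0.453 to 0.517), where even spread over the chromosome gives 0.109. At low-level pairs the values were 0.317 (0.290 to 0.350) and 0.233 (0.224 to 0.243). The mean over all pairs was 2.26 times higher in the NT library labelled control (2.07 to 2.47), opposite to the TdT preparation. The 10% of pairs with the most NT ends held 74.5% of the control ends and 42.8% of the iodine ends at the nick position; without them the ratio was 1.01 (0.983 to 1.04), and without the first 1% and 5% it was 1.71 and 1.25, but pairs were ranked by the ends compared. Counted pair by pair, the control had the higher scaled count at 52.6% of high-level pairs (51.0 to 54.2), 45.1% of low-level pairs (43.7 to 46.4) and 48.2% of all pairs (47.1 to 49.2). From 5 to 10 positions downstream of the site, the NT iodine library was the higher one, by 3.23 times at high-level pairs (3.03 to 3.43) and 1.15 times at low-level pairs (1.097 to 1.191).

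**Figure D2:**
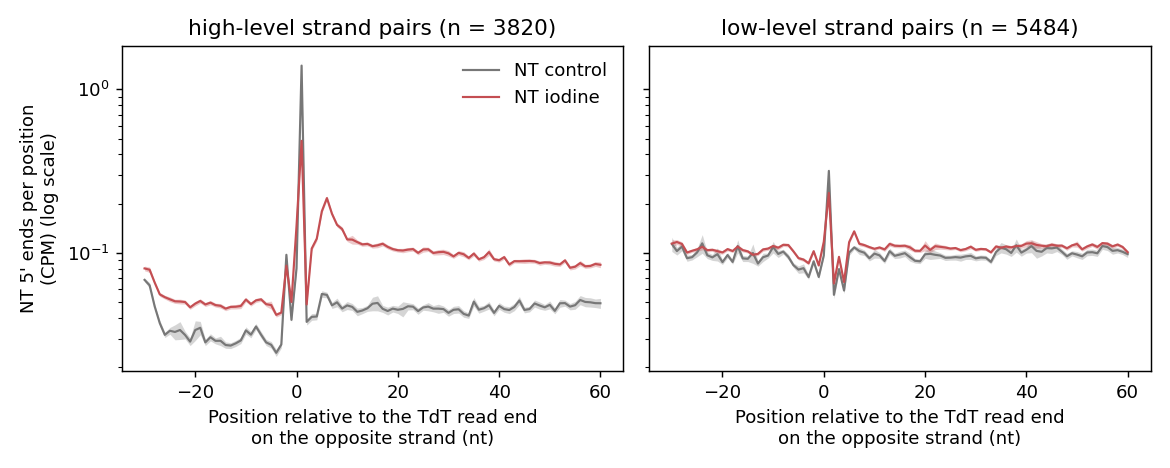
Mean NT 5′ ends per position in CPM (log axis) at each position from 30 upstream to 60 downstream in read direction, for the 3820 high-level and 5484 low-level strand pairs; lines are means and shading is 1 standard error over sites. The NT control reaches 1.39 at the nick position of high-level pairs against 0.484 in NT iodine, and the iodine library is higher 5 to 10 positions downstream.

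A broader NT signal lay upstream, where read starts piled up before high-level pairs. From 100 to 400 positions upstream, the NT control had a mean of 0.242 CPM per position, against 0.0626 at the same distance downstream, a ratio of 3.87 (3.69 to 4.01). By strand, the control ratio was 3.79 on the forward (3.55 to 4.01) and 3.94 on the reverse strand (3.72 to 4.14). The NT iodine library had 0.172 against 0.0820 CPM, a ratio of 2.10 (2.03 to 2.16). The fullest 25-position window lay 225 to 201 positions upstream in the control, at 0.301 CPM (standard error over sites 0.00646), and 175 to 151 upstream in NT iodine, at 0.208 CPM. The control had more starts upstream than downstream at 93.2% of high-level pairs (92.4 to 94.0) and NT iodine at 90.1% (89.1 to 91.0). At low-level pairs the upstream over downstream ratio was 0.908 in the NT control (0.871 to 0.943) and 0.935 in NT iodine (0.909 to 0.962), and at high-level pairs it was 1.06 in the TdT control (0.987 to 1.14) and 1.22 in TdT iodine (1.17 to 1.26).

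**Figure D3:**
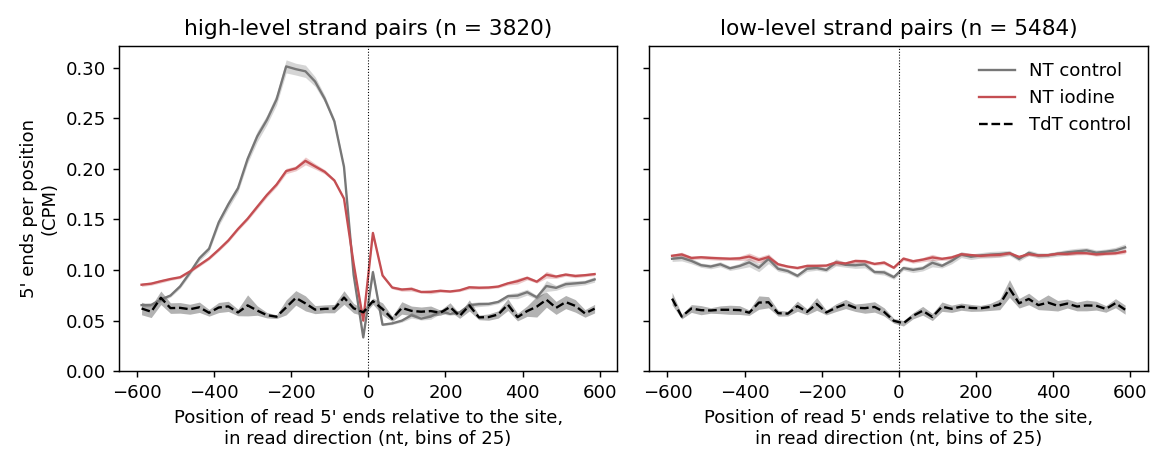
Mean 5′ ends per position in CPM, in windows of 25 positions, from 600 upstream to 600 downstream of the site in read direction, at high-level and low-level strand pairs; lines are means, shading is 1 standard error over sites, and the dotted line marks the site. In the NT control the mean rises to 0.301 before high-level pairs, and no such rise is seen at low-level pairs or in the TdT control.

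High-level pairs lay more evenly along the chromosome than random placement gives. Across 100 equal bins they numbered 38.2 on average, from 30 to 54, with a variance over mean of 0.457 (chi-square 95% interval 0.353 to 0.617), where random placement gives about 1. Low-level pairs numbered 54.8 on average, from 28 to 116, with a variance over mean of 4.19, and their number differed with read depth, though not part by part: of 10 equal parts of the chromosome, the 5 with a median NT control depth of 27 to 42 held 2442 and the 5 with a depth of 44 to 55 held 3042. High-level pairs numbered 1821 and 1999 in the same parts. The fullest low-level bin ran from 2393269 to 2439292. Neighbouring high-level pairs were 1203 positions apart on average, with a coefficient of variation of 0.446, against 0.952 to 1.06 in 1000 random placements. Gaps under 200 made up 1.39% of the gaps, against 13.6% to 16.8% at random, and the longest gap between high-level pairs was 4204 positions, from 222786 to 226990. Low-level pairs had a coefficient of variation of 1.21 and 29.7% of gaps under 200, above the 19.4% to 22.7% of random placement.

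**Figure D4:**
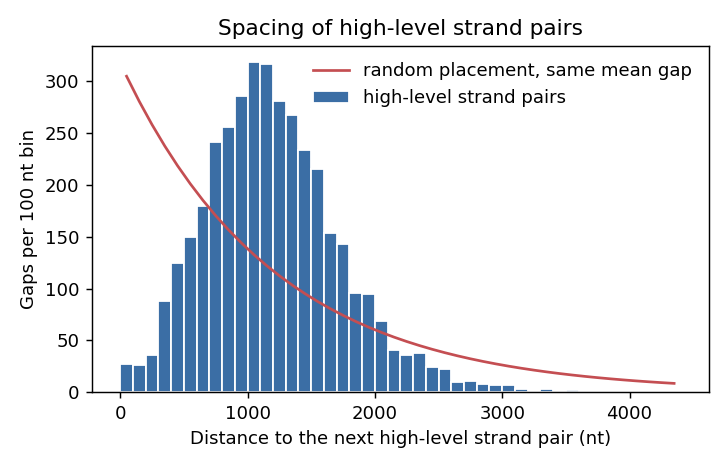
Number of gaps between neighbouring high-level strand pairs per 100-position step of gap length (bars) and the number expected of random placement with the same mean gap of 1203 (line). Gaps under 200 are 1.39% of all.

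**Figure D5:**
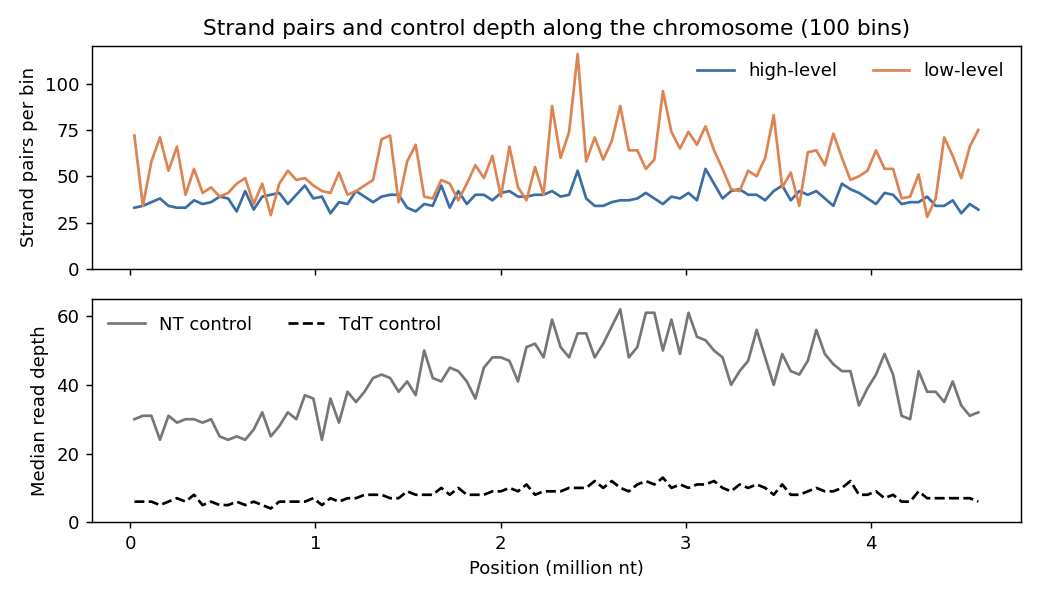
Top, high-level and low-level strand pairs in each of 100 equal bins along the chromosome; bottom, median read depth of both strands in the NT and TdT controls in the same bins. High-level pairs stay between 30 and 54 per bin while low-level pairs reach 116.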

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

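Of the tests in this part, the one across strands was set before its result was seen; the comparison at strand pairs and the other tests were chosen after the NT result had been seen. In the mean, iodine over control differed in direction between the preparations at the 9304 strand pairs: the scaled rate was 155 times the control's at the paired ends of the TdT preparation and 0.442 times the control's at the nick position of the NT preparation. Counted pair by pair, the NT control was higher at 4480 pairs and NT iodine at 4572, so over all pairs the NT reversal was one of the mean. At high-level pairs the control was higher at 2009 and NT iodine at 1710. Low-level pairs went the other way, with 2471 and 2862. The TdT direction was fixed by the call, which required iodine above control, so only the NT direction was free to vary. From 5 to 10 positions downstream of the same pairs, NT iodine was 1.69 times the control (1.62 to 1.76). With 1 library per group, the difference between the preparations was not tested.

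A difference in scaling between the NT libraries is argued against, because the control over iodine ratio 10 to 60 positions upstream was 0.925 (0.908 to 0.943) while it was 2.26 at the nick position. That a small share of sites carries the excess stays open: the ratio was 1.01 without the 10% of pairs with the most NT ends, which held 74.5% of the control ends and 42.8% of the iodine ends, while without the 10% with the most forward-strand ends the ratio on the reverse strand was 2.28 (1.93 to 2.72). Neither removal decides it, because the first ranks pairs by the NT ends that are then compared and the 10% of the second held 16.9% of the reverse-strand control ends. Exchanged labels of the NT libraries cannot be told apart from true ones: at the 524 pairs with a level of at least 1024 counts, ends 5 to 10 positions downstream were 1.84 times (1.67 to 2.02) those upstream in the library labelled iodine and 0.445 times in the control, but ends at the nick position were 5.30 and 15.3 times those upstream. A hypothesis is that bonds left uncut in the control stopped the exonucleases, so that strands ending at a modified site survived, but it stays open: starts upstream over downstream of high-level pairs had a ratio of 3.87 (3.69 to 4.01) in the control and also 2.10 (2.03 to 2.16) in NT iodine, where bonds should have been cut. The pile-up was at 93.2% of high-level pairs in the control, while 52.6% had the higher nick-position count there. A similar excess was also seen at the 200 fullest TdT control positions per strand, which were chosen by control count alone. There the NT control had 10.8 times as many ends on the other strand 20 to 200 positions into the TdT read as behind it.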

How the results depend on the processing

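Among the alternatives, those applied to strand pairs, to levels, to spacing and to the NT ratio were chosen after seeing the data. The number of high-level pairs stayed within 1.5 times the reported 3820 in all 10 alternatives (3295 to 4497). Only moving the border of the high level, to a log2 level of 6 or 8, changed that number by much. The number of strand pairs stayed within 1.5 times 9304 in 8 of 9 alternatives (6434 to 12673), and exchanging iodine and control gave 28 strand pairs. TdT sites stayed within 1.5 times 24377 in 6 of 8 alternatives and were 37228 without the control filter and 41187 without the local maximum rule. NT sites moved from 19258 to 81725 with a minimum count of 5, 3436 with 20, 9391 with a ratio of 4, 58714 without the control filter and 12253 with a pseudocount of 5. Shared sites moved from 343 under the same 5 alternatives to 996, 105, 173, 1324 and 221. For these the cause was not tested beyond what each rule admits or removes by construction. The coefficient of variation of high-level gaps was 0.487 with the border of the high level at a log2 level of 6 and 0.499 with it at 8, both outside its interval of 0.435 to 0.458, and stayed inside it in the other 8 alternatives. Those 8 changed only the calling rule and left 3812 to 3849 high-level pairs, so they could hardly move the coefficient. The NT control over iodine ratio at the nick position was 2.66 when scaled without positions at or above the 99th percentile, 1.66 without the 1% of pairs with the highest control count and 1.01 without the 10% with the most NT ends. The removal by control count lowers the ratio by construction; the other also ranks pairs by ends that enter the ratio, and its pairs held 74.5% of the control ends and 42.8% of the iodine ends. The variance over mean of high-level pairs was 0.511 in 50 bins and 0.398 in 200. Alternatives that need the genome sequence, such as leaving out repeats, were not run. No paired analysis was possible because each group has 1 library, and for the same reason no replicate could be left out. The NT calls had a median count of 12, next to the minimum of 10, and pairs with fewer than 20 added ends were not simulated, so what the depth allows below that is not known.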

Other observations

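Apart from the test of outward-facing read ends and the ranking by NT control ends, the tests in this part were chosen after the results had been seen. Low-level pairs were also called less often near high-level pairs. Their median distance to the nearest high-level pair was 427 positions, against 317 for random positions, and 20.2% (19.2 to 21.3) lay within 200 positions, against 32.5% (32.2 to 32.8) of random positions. TdT iodine ends were themselves fewer there: 0.0274 CPM per position 100 to 76 upstream of high-level pairs, against 0.0561 at 600 to 576 upstream. The TdT control had 0.0619 and 0.0620. Whether low-level pairs were absent there or harder to call cannot be told apart. Among low-level pairs at least 6 and under 300 positions apart, 40.1% of distances were multiples of 3 (38.4 to 41.9), and among all pairs 39.5% (38.2 to 40.9); among high-level pairs it was 34.4% of 96 distances (25.6 to 44.3). Control depth followed a gradient along the sequence: over 10 equal parts of the chromosome, the median NT control depth was lowest at 27 between positions 460244 and 920487 and highest at 55 between 2761464 and 3221707, and the TdT control ran from 5 to 11 over the same parts. High-level pairs per part numbered 348 to 408 and low-level pairs 432 to 723.

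The TdT control was dominated by a small set of positions. The 10 fullest positions of each strand held 30.2% of its ends, and 16 of these 20 were also among the 10 fullest of their strand in the TdT iodine library. The fullest was at 3835204 on the reverse strand, with 215866 ends in the control and 61431 with iodine, followed by 2874189 on the forward strand with 208241 and 53655. Over the 200 fullest TdT control positions per strand, the NT control had 784145 ends on the other strand 20 to 200 positions into the TdT read and 72412 at the same distance behind it, a ratio of 10.8.

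The 2 levels of strand pairs were weighed against technical sources. Chance pairs of unrelated read ends are argued against by the fullest other offset, which held 141 pairs against 5484 low-level pairs. Local read depth, as far as the NT control shows it, is argued against. Its median within 500 positions was 1.28 times (1.24 to 1.31) as high around high-level as around low-level pairs, while the pairs' median levels differed 20.7 times. The NT control also piled up starts before high-level pairs, so its depth is not independent of the level. TdT control ends 100 to 400 positions away averaged 0.0620 CPM upstream and 0.0583 downstream at high-level pairs, against 0.0623 and 0.0664 at low-level pairs. Depth in the TdT iodine library, which sets the levels, was not tested. A bias of the TdT preparation alone is argued against by the NT control. Its ratio of starts upstream over downstream was 4.26 times (4.02 to 4.50) as high at high-level as at low-level pairs. Close high-level neighbours lower that ratio and the 2 levels were not matched for them, so the size of the 4.26 is uncertain. With another high-level pair under 600 positions away, the ratio at high-level pairs was 1.76 (1.64 to 1.89). At all low-level pairs it was 0.908 (0.871 to 0.943). A candidate explanation, which no test here reached, is that high-level pairs are modified in most DNA copies and low-level pairs in few; no measure of the modified fraction was used here.

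The even spacing of high-level pairs was weighed in the same way. Loss of short fragments between neighbouring nicks would leave the outward-facing reads of close pairs in place, but outward-facing high read ends under 200 positions apart numbered 118 against 642 of independent placement, a ratio of 0.184 (Poisson 95% interval 0.152 to 0.220). The even spacing was not shared by the strand pairs as a whole. The lowest coefficient of variation among 1000 random draws from all pairs was 0.909, above the observed 0.446. These draws do not show where callable positions lie, which needs the sequence, so the placement of all callable sites stays open as a source. Whether the spacing is a feature of TdT levels alone was asked by ranking pairs on the NT control: the 3820 pairs with the most NT control ends had a coefficient of variation of 1.00, inside the range of draws, but the ranking hardly separated the levels, with 47.9% of its pairs high-level against 41.1% of all. Ranked by NT control starts 100 to 400 positions upstream over downstream, the coefficient was 0.720, but the question stays open, because close neighbours lower that ratio: it was 1.76 (1.64 to 1.89) at high-level pairs with another under 600 positions away and 5.14 (4.92 to 5.36) at the others. That modification of 1 site lowers the chance of full modification nearby may be considered as a hypothesis; the design holds no strain or condition that tests it.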
